A study of Caenorhabditis elegans with 4 samples.

How the data were processed

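ChIP-seq was done on L1 hermaphrodites of strain OP322, which carries a GFP-tagged ztf-4 transgene and an unc-119 rescue marker in an unc-119 mutant background. Per the labels' protocols, worms were grown at 20 °C, fixed with 2% formaldehyde and sonicated. About 10% of the lysate was kept as input, and the rest was incubated with affinity-purified goat antibodies against GFP. The stage label also gives 26 °C beside L1, and which temperature applied to these cultures was not settled. Samples were grouped by their titles into 2 ChIP and 2 input libraries. The free-text descriptions name the antibody on the input libraries and call the ChIP libraries input DNA, opposite to the titles and source names. The titles were followed, because the peak lists belong to the libraries titled ChIP. The input libraries have no values here and enter no comparison. The labels do not say whether replicates 1 and 2 came from separate cultures, so whether they differ biologically or only technically is unknown.

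The deposited values are peak intervals, each with a q-value as its own score. Per the file headers, coordinates are in the WormBase build WS180, and the source column names PeakSeq as the caller. The q-values deposited by the authors stand in the score column and again as an attribute of each peak, and they run up to 5.03e-05 in replicate 1, 5.36e-05 in replicate 2 and 7.51e-05 in the combined list. The aligner, read filters, depth, threshold and PeakSeq version are not given in the sources used here. It is also not given how input libraries entered the calling, or whether the combined list was called on pooled reads. A q-value depends on depth, so it was used only to rank, describe and filter peaks within its own list. A longer combined list can arise from a larger number of reads alone.

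Peaks were taken as overlapping when they shared at least 1 bp. Overlap was tested with 10000 circular shifts of one list, by an amount drawn for each chromosome, which keep widths and spacing on a circle that ends at the farthest peak of any list. The test was tried on simulated lists of 379 and 394 peaks. It called all 400 of 400 simulated pairs in which 5% of the peaks had been planted as shared, and 8 of 400 pairs with none, with 1000 shifts each. The simulated peaks were placed uniformly, without the grouping of the real peaks, so these rates need not hold for the real lists. Correlations across peaks used 100000 permutations. Shares on chromosomes and in the arms (the outer 25% of the length at each end) were tested with exact binomial tests, adjusted by Benjamini-Hochberg over the 6 chromosomes. Chromosome lengths are lower bounds, from 13.8 Mb for III to 20.8 Mb for V and 99.3 Mb in all, since no sequence of this build was used here. Intervals are 95% Clopper-Pearson intervals over peaks and cover counting error only. The p-values refer to positions and peaks within these lists, not to variation between animals or cultures, and neighbouring peaks are not independent. The calculations used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3. Figures were drawn with matplotlib 3.10.9.

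The designs of the overlap, support, score, X chromosome and arm results, and the alternatives for them, were fixed before the data were examined, except for the chromosome lengths. Lengths were planned from a reference, and the farthest peak ends in the lists were used in their place. The tests of the other chromosomes and of X against the autosomes were added afterwards. Alternatives were a reciprocal overlap of 50%, midpoints within 200 bp, the better 50% of each list by q, lists of equal length, the rank correlation without the 10 best peaks, uniform placement, each replicate list on its own, only peaks found in both lists, and wider arms with an expected share of 66.7%. Added afterwards were a local shift of each peak by 2000 to 50000 bp, the span from first to last peak as length, and counting runs of peaks within 5000 bp once. The regions named are the 20 best combined peaks by q that overlap both replicate lists, a rule also fixed beforehand, with the 10 best given in full. The peak lists pair no interval with a gene, and the only gene table at hand is of another assembly (WBcel235). Coordinates were not carried between builds, so genes near peaks, promoter shares, gene lists, sequence content and the ztf-4 and unc-119 loci were not analysed here.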

Results

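The binding of ZTF-4, a zinc-finger protein of the nematode Caenorhabditis elegans, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in hermaphrodites at L1, the first larval stage. The worms (strain OP322) carried a transgene that encodes ZTF-4 with a green fluorescent protein (GFP) tag, so that chromatin bound by the tagged protein could be collected with an antibody against GFP. The series holds 2 immunoprecipitated libraries and 2 input libraries, the input being total chromatin DNA set aside before the immunoprecipitation. The measurements examined were the authors' peak lists: 379 peaks for replicate 1, 394 for replicate 2 and 855 in a combined list. Peaks had a median width of 739 bp in replicate 1, 687.5 bp in replicate 2 and 695 bp in the combined list, and together they covered 385 kb, 367 kb and 875 kb. No read counts accompanied the peaks, so the sequencing depth behind each list is unknown.

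Whether the same sites were found in both immunoprecipitations was examined first. Of the 379 peaks of replicate 1, 299 overlapped a peak of replicate 2, or 78.9% (95% exact binomial interval 74.4 to 82.9%). In the other direction, 305 of the 394 peaks of replicate 2 overlapped a peak of replicate 1, or 77.4% (73.0 to 81.4%). When the peaks of replicate 1 were moved together along each chromosome, a mean of 2.91 of them overlapped replicate 2 by chance, and the highest of 10000 such shifts gave 48. The overlap was therefore larger than in every shift (one-sided permutation test, p = 0.0001, the smallest that these shifts can give), in either direction. The best 100 peaks of each list by q-value all overlapped a peak of the other list. The peaks found in 1 list alone were weaker and narrower. The 80 peaks found in replicate 1 alone had a median q of 4.65e-06 and a median width of 654.5 bp, against 1.02e-08 and 760 bp for its shared peaks. The 89 peaks found in replicate 2 alone had a median q of 1.49e-05 and a median width of 524 bp, against 8.91e-09 and 767 bp. Across the 279 peaks that overlapped 1 to 1, the order by q-value was similar in both lists (Spearman's rho = 0.72, two-sided permutation test over peaks, p = 1e-05, the smallest that the permutations can give). This correlation runs across peaks, which are not independent replicates.

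The combined list was compared with the replicate lists to see how far each of its peaks rested on 1 or both immunoprecipitations. It contained 375 of the 379 peaks of replicate 1 and 388 of the 394 of replicate 2. Of its 855 peaks, 284 overlapped a peak in both replicate lists (33.2%, interval 30.1 to 36.5%), 75 only in replicate 1, 82 only in replicate 2, and 414 in neither (48.4%, interval 45.0 to 51.8%). The share found in both lists fell as the authors' q-value rose. With the combined list divided into 5 equal groups by q-value, 165 of the 171 best peaks (q up to 3.51e-15) were found in both replicate lists (96.5%, interval 92.5 to 98.7%). This number was 107 of 171 in the second group, 12 of 171 in the third and 0 of 171 in each of the fourth and the fifth. The replicate lists end at q = 5.03e-05 and 5.36e-05, so a weak combined peak may fall short in each replicate. If the combined list was called on pooled reads, such a decline could follow from that limit, and it does not measure reproducibility alone. Peaks in both lists had a median width of 1063 bp, and those in neither 567 bp. The best-ranked peak without any counterpart in the replicate lists stood at rank 146 of the combined list, with q = 1.02e-16. This peak, on chromosome II from 8478231 to 8480539, was not an isolated site. It lay within 1000 bp of the combined peak from 8480948 to 8482220 (rank 104), which was found in both replicate lists.

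**Figure D1:**
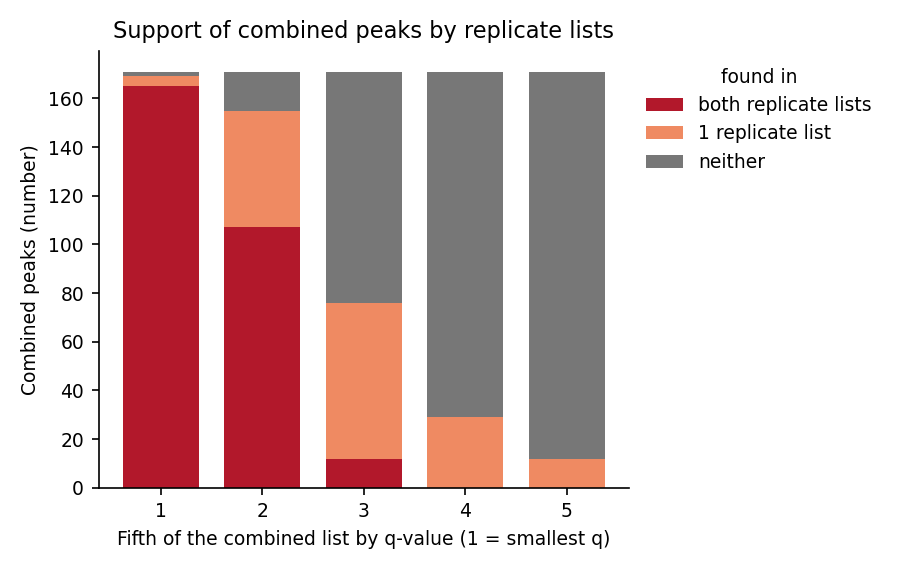
Number of combined-list peaks (vertical axis) in each of 5 equal groups of the list by the authors' q-value (horizontal axis, 1 being the smallest q), coloured by whether they overlapped a peak in both, 1 or neither of the replicate lists. Peaks found in both lists make up 165 of 171 in the best group and 0 of 171 in the fourth and the fifth.

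The regions with the smallest q-values were broad and were found in both replicates. The ztf-4 and unc-119 loci were not located in this build. Whether any region named here holds DNA of the transgene or its marker was therefore not checked. The smallest q-value of the combined list belonged to chromosome X, 4141991 to 4149129 (all coordinates are in the WormBase build WS180), with q = 2.87e-215. The same region was the first by q in replicate 2 (q = 1.63e-104) and the second in replicate 1 (q = 3.4e-101). It was followed by chromosome I, 7078707 to 7086225 (q = 4.74e-209), and by chromosome II, 10541824 to 10554289 (q = 6.84e-186), which led the list of replicate 1 (q = 1.81e-101). Next came chromosome V, 6220746 to 6229991 (q = 1.12e-147), chromosome X, 16929274 to 16931999 (q = 7.39e-133), and chromosome V, 723453 to 728370 (q = 1.5e-127). These 6 regions were also the first 6 of each replicate list. Positions 7 to 10 were taken by chromosome II, 14599105 to 14609768 (q = 2.74e-111), chromosome X, 6736217 to 6745269 (q = 2.3e-102), chromosome X, 6252037 to 6256722 (q = 1.59e-100), and chromosome I, 7656464 to 7660472 (q = 3.59e-92).

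Of the 20 best peaks of the combined list, all of which overlapped peaks in both replicate lists, 6 lay on chromosome II, 6 on X, 4 on I, 2 on V, 1 on III and 1 on IV. The regions on IV and III were 14032535 to 14035053 (q = 9.09e-82) and 9050822 to 9054237 (q = 3.71e-61). Widths in this group ran from 913 bp, on chromosome X from 8035964 to 8036876, to 12466 bp, and 14 of the 20 reached 3000 bp. In 10 of the 20, at least 1 replicate list divided the region into 2 or more peaks. Over the whole combined list, 33 peaks reached 3000 bp. These were 3.86% of the peaks and 18.6% of the covered sequence, 29 of them were found in both replicate lists, and 31 were among the 171 best peaks by q. Wider peaks had smaller q-values across the 855 peaks (Spearman's rho = 0.52, two-sided permutation test over peaks, p = 1e-05, the smallest possible). Each q-value scores a whole interval, so width and q are not independent measures. Whether width alone lowers q was not tested.

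**Figure D2:**
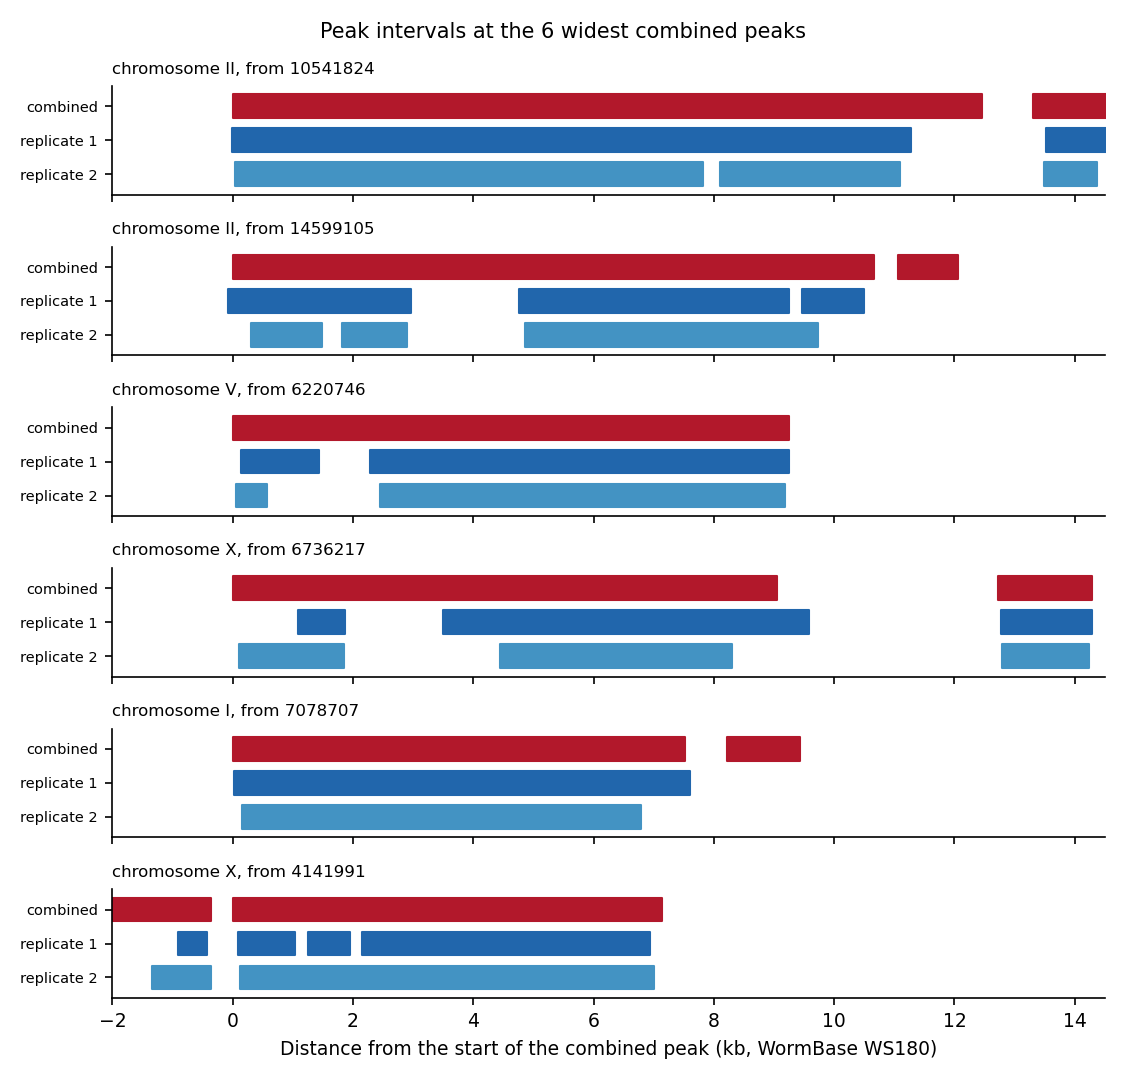
Peak intervals at the 6 widest combined peaks, by distance in kb from the start of the combined peak (horizontal axis), with 1 line each for the combined list, replicate 1 and replicate 2, and neighbouring peaks shown only as far as the edges of the plot. The chromosome II region of 12466 bp is covered by 1 peak in replicate 1 and 2 in replicate 2, and the region from 14599105 by 3 peaks in each.

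Where in the genome the peaks lay was compared with the length of each chromosome, taken as the position of its farthest peak in any list. Chromosome III held the most peaks for its length. It carried 174 of the 855 combined peaks, or 20.4% (interval 17.7 to 23.2%), against 13.9% of the length (two-sided exact binomial test, p = 1.82e-07, adjusted over the 6 chromosomes 1.09e-06). This was 12.6 peaks per Mb. The share on III was 21.1% in replicate 1 (80 peaks, adjusted p = 0.000627, exact binomial test) and 23.4% in replicate 2 (92 peaks, adjusted p = 2.33e-06, exact binomial test). Chromosome V carried 139 peaks, or 16.3%, against 20.9% of the length (exact binomial test, adjusted p = 0.00195), the lowest density at 6.69 peaks per Mb. The shortfall on V did not pass the test in replicate 1 (18.5%, adjusted p = 0.464, exact binomial test) or in replicate 2 after adjustment (16.2%, adjusted p = 0.0655, exact binomial test). The X chromosome held 129 peaks, or 15.1%, against 17.6% of the length, which missed the threshold (exact binomial test, p = 0.0535, adjusted 0.107). Its share was 19% in replicate 1 and 15.5% in replicate 2, on either side of its share of the length. The shares of I, II and IV did not differ detectably from their lengths (15.7%, 13.2% and 19.4%, adjusted p = 0.599, 0.152 and 0.152, exact binomial tests). These tests treat peaks as independent, although many lie close together.

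Within the autosomes, more peaks than expected from length alone lay towards the middle of the chromosomes. How genes, or sequence to which reads can be assigned, are spread along the chromosomes was not taken into account. Of the 726 autosomal combined peaks, 261 had their midpoint in the arms, taken as the outer 25% of the length at each end, or 36% (interval 32.5 to 39.6%), against an expected 50% (two-sided exact binomial test, p = 3.36e-14). The share was 38.4% in replicate 1 (118 of 307 peaks, p = 6.03e-05, exact binomial test) and 36.9% in replicate 2 (123 of 333, p = 2.15e-06, exact binomial test). Among single autosomes, the arm share was 28.8% on V (adjusted p = 3.57e-06), 33.3% on III (adjusted p = 3.92e-05), 37.3% on I (adjusted p = 0.00838) and 38.1% on II (adjusted p = 0.0211), each by an exact binomial test adjusted over the 6 chromosomes. Chromosome IV, at 42.2%, missed the threshold (adjusted p = 0.0624, exact binomial test). On the X chromosome 68 of 129 peaks lay in the arms, or 52.7% (interval 43.7 to 61.6%; exact binomial test, p = 0.597). The arm share on X was higher than that of the autosomes (Fisher's exact test, two-sided, odds ratio 1.99, p = 0.000392), as it was in replicate 1 (54.2% against 38.4%, p = 0.0169, Fisher's exact test) and in replicate 2 (57.4% against 36.9%, p = 0.0042, Fisher's exact test). With neighbouring peaks within 5000 bp counted once, the shares were 52.5% and 38.2% (Fisher's exact test, p = 0.00799). The Fisher tests pool the autosomes, whose single shares in the combined list ran from 28.8 to 42.2%. They therefore do not measure how unusual X is among single chromosomes.

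**Figure D3:**
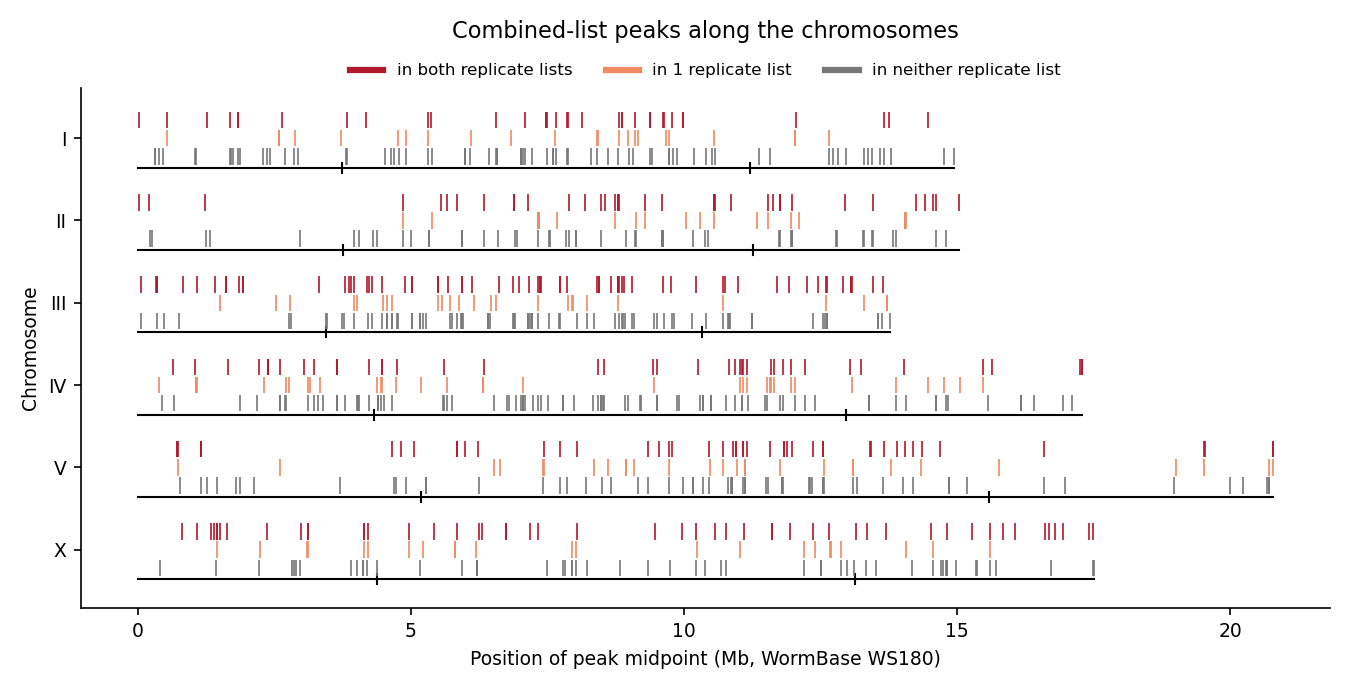
Midpoints of the 855 combined-list peaks (vertical strokes) along the 6 chromosomes, by position in Mb in WormBase WS180 (horizontal axis), on separate levels for peaks found in both, 1 or neither of the replicate lists. Each black line ends at the farthest peak, and its ticks mark the limits of the arms, which hold 36% of the autosomal peaks and 52.7% of those on X.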

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

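The local shift, the span from first to last peak as chromosome length, counting runs of neighbours once, and all alternatives for the shares on chromosomes III and V were chosen after seeing the data. Replicate overlap (6 of 6 alternatives in each direction), the correlation of q-value ranks (2 of 2), the autosomal arm share (6 of 6) and the share on III (6 of 6) kept their direction and their side of the threshold, by unadjusted p, under the alternatives run. Overlap of replicate 1 peaks ranged from 63.3% with midpoints within 200 bp to 80% in the better 50% of each list, and under the local shift chance overlap was 2.24% of its peaks. With runs counted once the share on III was 20% (exact binomial test, p = 2.24e-05). The number of combined peaks found in both lists was 190 to 280 under the other overlap rules and with lists of equal length, and 146 with the better 50% of each replicate list, which shortens the lists by construction. The X share lay above its share of the length in place of below it in replicate 1 alone and among peaks found in both lists (18%), with a range of 15.5 to 19% over the single replicate lists, and passed the threshold in none. The cause was not tested. The shortfall on V, with 16.2 to 18.5% over the single replicate lists, lost the threshold by unadjusted p in replicate 1 alone (exact binomial test, p = 0.256) and among peaks found in both lists (17.3%, exact binomial test, p = 0.144). In replicate 2 alone it passed by unadjusted p and not after adjustment over the 6 chromosomes (exact binomial test, p = 0.0218, adjusted 0.0655). It passed in the better 50% of the combined list, at 15.9% of 428 peaks (exact binomial test, p = 0.0105). That set is larger than either set in which the unadjusted threshold was lost, so it cannot show whether fewer peaks alone ended the call. The cause was not tested. No paired analysis was possible because the input libraries have no values here. Not run for want of a WS180 annotation were placement by distance to genes, gene numbers as the expectation for X, and every alternative for promoters, gene lists and sequence. Depth is unknown, so a site missing from a list is not shown to be unbound.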

Other observations

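The spacing and bridging of close peaks, the permutation of all replicate-only peaks and that without 1 Mb of chromosome II, the runs, the densest windows, and the rule that both versions of the test by eighths must give the same answer were chosen after the results were seen. Peaks lay in groups. With gaps of up to 5000 bp, the 855 combined peaks formed 625 runs, of which 161 held 2 or more peaks and 50 held 3 or more. The longest by number was chromosome V, 12548710 to 12557684, with 6 combined peaks, 3 peaks in replicate 1 and 2 in replicate 2. Runs of 5 lay on chromosome X, 4132205 to 4149129, which contains the combined peak with the smallest q, on chromosome III, 8794595 to 8806504, and on chromosome II, 7336733 to 7349064. The densest windows of 1 Mb held 23 combined peaks each, on III from 5000001 to 6000000 and on IV from 11000001 to 12000000, against a median of 8. Counted as runs, the highest number in a window was 15, below the 95th percentile of 18 for the highest window under uniform placement that kept the number of runs on each chromosome. Only the highest window was compared, and windows on chromosomes with fewer runs were not tested singly.

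A region on chromosome II was called in 1 replicate alone. In replicate 2, 7 peaks between 7336721 and 7349004 covered 7889 bp of 12284 bp, the best of them at rank 120 with q = 4.31e-10, and replicate 1 had no peak there. Of the 18 runs of 3 or more peaks in replicate 2 this was the only one without a peak in replicate 1, and each of the 18 such runs of replicate 1 had a peak in replicate 2. In the combined list the region appears as 5 peaks with a best q of 2.53e-13. The cause was not tested.

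The chromosomes of the replicate-only peaks differed between the lists; the whole lists gave p = 0.422 (permutation test), but most of their peaks are shared sites, which lie on the same chromosomes by definition. Replicate 1 alone had 5 peaks on II, 8 on III, 19 on V and 17 on X, and replicate 2 alone had 20, 19, 11 and 8. Moving the list labels over the 169 peaks gave a chi-square as large in few draws (permutation test, p = 0.00061). That argues against a chance division but does not exclude it. The test was chosen after the counts were seen, and it takes neighbouring peaks as independent. Repeated counting of neighbours may carry part of the difference. With runs counted once the chi-square fell from 20.9 to 13.3, with p = 0.0196 (permutation test). Leaving out the 1 Mb of chromosome II that holds the region above gave p = 0.0117 (permutation test). The comparison was chosen after the results were seen, so neither value excludes repeated counting outright. Calls near the threshold stay open, because only 13 of these peaks lie in the better 50% of their list (permutation test, p = 0.198), and no biological explanation was tested.

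Close pairs may in part be single regions divided by the caller. In the combined list 108 adjacent pairs lay within 1000 bp of each other, against a mean of 15.3 and a maximum of 28 in 1000 uniform placements (permutation test, p = 0.001, the smallest possible), which argues against chance spacing. Of such pairs, 13 of 35 in replicate 1 and 19 of 42 in replicate 2 were spanned by 1 combined peak. Pooled over both lists this was 32 of 77, or 41.6% (interval 30.4 to 53.4%). Some regions enter from both lists, so the pooled pairs are not independent and the interval is too narrow. How the combined list was called is unknown, so a span does not tell 1 divided region from separate sites joined in that list. The remaining pairs and the 108 of the combined list cannot be told apart from separate sites either. No further list among the files used here could span them. No biological explanation was tested.

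Combined peaks found in neither replicate list were looked at by eighths of each chromosome, with both versions of the test set before they were run but after the counts by eighth had been seen. On IV from 6480736 to 8640981, 21 of 24 combined peaks had no counterpart, but 16.7 were expected from their q-values (permutation within the 5 groups by q, adjusted over 48 eighths, p = 0.25). The largest excess was on I from 5604934 to 7473244, with 14 of 19 against 9.56 expected (permutation test, adjusted p = 0.0571). With only the best peak of each run it was 10 of 13 against 5.55 (permutation test, adjusted p = 0.007), which argues against repeated counting of neighbours. By the criterion set beforehand the p of 0.0571 alone would leave the excess to weak calls, but the versions disagree, so weak calls and a regional effect cannot be told apart, and no biological explanation was tested.

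Of the 10 replicate peaks missing from the combined list, 4 form matching pairs in both replicates, on chromosome I at 3171486 to 3172047 (q = 5.39e-06 in replicate 1 and 6.71e-06 in replicate 2) and on chromosome III at 931226 to 931680 (q = 6.19e-06 and 2.07e-05). Their bounds differ by at most 2 bp between the replicates.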
